A study of Danio rerio with 5 samples.

How the data were processed

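Messenger RNA was measured by poly(A)-selected, strand-specific RNA sequencing of whole zebrafish embryos, with 5 libraries of 15 embryos in 5 groups of 1. Per the submitters' processing notes, CASAVA 1.8.2 and TopHat2 2.0.8 were used with the zebrafish build Zv9 (danRer7). The counting tool, the annotation release, the use of strand and the treatment of multiply mapped reads are not given in the sources used here. Each deposited table holds 26158 Ensembl gene identifiers with a length, 3 count columns and 3 RPKM columns, per the file headers. The main values are the authors' whole-number read counts per gene, deposited without normalization. A further deposited column holds estimated counts with fractional parts, not whole (tolerance 1e-06) in 3838 to 4207 genes per library, which was used rounded to whole numbers as an alternative. The authors' RPKM values were per kilobase of the length column and relative to the sum of the matching count column, as recomputed from the deposited columns, and were used as an alternative only.

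Gene symbols came from a table that pairs identifiers with symbols; 18804 of the 26158 identifiers had one, and the others held 12.4% to 12.9% of the counts. Several symbols belong to more than 1 identifier, in which case the identifier is given. Genes that share reads with near-identical copies or overlap other genes are uncertain, since it is not known how such reads were counted. Of the fixed genes, parn was not matched to an identifier and is not analysed here. The gene lists, which hold older names beside current ones for some genes, also lost symbols, and the tallies cover the measured identifiers only. The symbols listed, identifiers matched and identifiers measured were 12, 7 and 6 for the literature targets, 39, 29 and 28 for maternal and oocyte genes, 14, 10 and 9 for germ plasm, 21, 10 and 9 for dorsal organizer, 27, 12 and 12 for mesoderm and endoderm, 10, 6 and 6 for Nodal, 13, 5 and 5 for BMP and ventral, 17, 9 and 9 for epiblast, 16, 11 and 11 for enveloping layer, 13, 8 and 7 for yolk syncytial layer, 22, 16 and 8 for segmentation-stage, 15, 11 and 10 for p53, 14, 11 and 5 for interferon, 27, 15 and 15 for small RNA machinery, 18, 14 and 14 for reference genes, and 19, 7 and 1 for tissues not formed at this stage. The values of 1 list member are not reported here.

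From the counts, TMM factors over the 5 libraries were computed with edgeR 4.0.16 in R 4.3.3 and ranged from 0.967 to 1.02. A gene was measured when its mean TMM-scaled CPM over the 5 libraries was at least 1 (14097 genes). Ratios are differences of log2(CPM + 0.5), which understate the difference of low genes, and folds of named genes are ratios of CPM without the pseudocount. A gene was called higher or lower when the ratio was at least 2-fold and the 95% exact conditional binomial interval of the 2 counts excluded equality. Intervals and floors cover counting error only. They may be too narrow even for that, since reads without molecular identifiers are not independent molecules. A count of 0 was replaced by a floor of 3 counts per library, which is 0.118 CPM in wild type and 0.201 CPM in MZdicer, and the fold is then a lower bound. With 1 library per group there is no test between conditions, and no p-value was computed.

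The 7 comparisons, the settings above, 16 gene lists and the rule for named genes were set before the data were examined. The rule takes, per comparison, the 10 higher and 10 lower genes with a real symbol whose interval bound nearest to equality is largest, DICER1, parn and AGO2, up to 4 members of each list with the largest ratios, and all measured literature targets of miR-430. List medians have a binomial order-statistic interval over genes, and were ranked among 10000 random lists of the same size matched on mean expression in 20 bins. RRM2 values in all libraries, fthl28 and the genes seen only in the fractional column were singled out after their values were seen.

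The calling was tested on simulated counts for 14097 genes with 200 changed genes. For MZdicer against wild type 93 of 100 genes changed 2.83-fold and 99 of 100 changed 8-fold were called, with 3 unchanged genes called. For the duplex against MZdicer 90 and 98 of 100 were called, for the hairpin against MZdicer 96 and 98, for the 3xPS hairpin against MZdicer 89 and 99, for the 3xPS hairpin against the hairpin 96 and 98, for the hairpin against the duplex 94 and 97, and for the 3xPS hairpin against the duplex 96 and 96. These simulations hold counting error only. Chance sharing through the MZdicer library was simulated with 20 draws at each of 3 assumed coefficients of variation. For the 3xPS hairpin 20 draws were also made at 0.166, set from the spread between the 3xPS and MZdicer libraries.

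Alternatives were total-count scaling, DESeq2 1.42.0 size factors, upper-quartile factors, other filters and pseudocounts, the authors' RPKM, a 1.5-fold threshold, thinning to the smallest total and a split of the MZdicer counts. The fractional count column, a gene-length adjustment and the alternatives for the MZdicer-low genes were chosen after seeing the data. The planned comparison of genes with and without miR-430 sites in their 3′ untranslated regions needs sequences that were not used here and was not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.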

Results

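Poly(A)+ RNA was measured in whole zebrafish embryos at 6 h after fertilization, the shield stage of gastrulation, in 5 groups with 1 library of 15 pooled embryos each. The groups were wild type, embryos lacking maternal and zygotic Dicer (MZdicer), and MZdicer embryos injected with 1 of 3 forms of miR-430, the microRNA family that the early zygotic genome makes in large amounts. Dicer cuts microRNA precursors, so MZdicer embryos lack mature miR-430. The injected molecules were a miR-430 duplex, a hairpin that is cut by Argonaute 2 (Ago2) in place of Dicer, and the same hairpin with 3 phosphorothioate bonds (3xPS hairpin), all injected as 1 nl of a 25 µM stock. Total gene counts were 26300080 in wild type, 14867084 in MZdicer, 25317886 with the duplex, 24123349 with the hairpin and 24623675 with the 3xPS hairpin. Of 26158 genes in the tables, 14097 were measured. Because each group has 1 library, no difference has a replicate check and no p-value is given. Every statement compares libraries, and the 95% intervals in square brackets cover counting error only for single genes, and the spread over genes for medians.

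DICER1 (ENSDARG00000001129), the gene mutated in MZdicer fish, was at 36.5 CPM in wild type and 22.7 CPM in MZdicer, which was 1.61-fold lower [1.42, 1.83]. It was at 22.5 CPM with the duplex, 20.1 CPM with the hairpin and 23.0 CPM with the 3xPS hairpin. The counts cover the whole gene and do not show whether the transcript carries the mutation. AGO2 (ENSDARG00000061268), the Argonaute with slicer activity, was 2.58-fold higher in MZdicer than in wild type [2.49, 2.66], and was at 444 CPM with the duplex, 590 CPM with the hairpin and 675 CPM with the 3xPS hairpin.

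The comparison of MZdicer with wild type asks which transcripts differ without Dicer. The labels give the same time after fertilization for both libraries. A difference of stage or of strain between them cannot be told apart from the loss of Dicer here. Several literature targets of miR-430 and oocyte transcripts were higher in MZdicer, with 4 of 6 and 11 of 28 list members called. CCNA1 (ENSDARG00000043236), a cyclin of the oocyte and early embryo, was 19.9-fold higher [18.8, 21.1], the Nodal ligand ndr1 (ENSDARG00000057096) 13.7-fold higher [10.5, 18.2], and the Nodal antagonist lft2 (ENSDARG00000044059) 5.72-fold higher [5.09, 6.45]. The germ plasm organizer buc (ENSDARG00000096095) was 23.0-fold higher [19.8, 26.8]. Of 12 mesoderm and endoderm, 8 segmentation-stage and 9 dorsal organizer genes, 5, 6 and 3 were lower, among them the presomitic regulators mespaa (9.99-fold [7.51, 13.6]) and msgn1 (5.60-fold [5.04, 6.23]) and the BMP antagonist chrd (2.38-fold [2.28, 2.49]).

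Of 6 measured literature targets of miR-430, from 12 listed symbols of which some are older names, 4 were at least 2-fold higher in MZdicer and 0 lower, with a median log2 ratio of 1.87 [-0.24, 4.30]. The germ granule gene tdrd7a (ENSDARG00000032808) was 2.43-fold higher [2.21, 2.66], while lft1 had a ratio of 1.29 [1.17, 1.43] and NANOS3 was 1.19-fold lower [1.02, 1.38]. Among 28 maternal and oocyte genes, 11 were higher and 1 lower. GDF9, an oocyte growth factor, was 11.5-fold higher [8.10, 16.8] and cth1 3.85-fold higher [3.58, 4.13]. Of 9 germ plasm genes 4 were higher and 0 lower, including DAZL (2.65-fold [2.24, 3.15]). The 15 small RNA machinery genes had 8 higher and 0 lower, with a median of 1.03 [0.02, 1.87]. AGO1 was 6.82-fold higher [5.41, 8.66], ago3a 5.79-fold higher [4.65, 7.26] and DGCR8, the Drosha partner, 3.72-fold higher [3.54, 3.92]. In the Nodal pathway 3 of 6 genes were higher and 0 lower, the third being SMAD2 (3.97-fold [3.66, 4.30]).

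Of 8 segmentation-stage markers, 6 were lower and 0 higher, with a median of -2.09 [-2.54, -0.23]. The muscle regulator MYF5 was 13.8-fold lower [5.22, 51.8] and cdx4 4.94-fold lower [4.54, 5.39]. MYF5 had 4 counts in MZdicer (0.267 CPM), on which its folds against MZdicer in each injected library also rest. Of 12 mesoderm and endoderm genes 5 were lower and 0 higher, and of 9 dorsal organizer genes 3 were lower and 0 higher, OTX2 by 9.47-fold [5.16, 19.3]. Of 5 BMP and ventral genes 2 were lower, eve1 by 2.78-fold [2.60, 2.97] and GATA2 by 2.43-fold [2.27, 2.60]. Of 11 enveloping layer genes, which mark the outer epithelium, 3 were lower and 0 higher, among them epcam (3.03-fold [2.89, 3.18]) and krt5 (2.43-fold [2.38, 2.47]). The 9 epiblast genes went both ways. The pluripotency factor nanog was 6.12-fold higher [5.84, 6.43] and sox19b 3.13-fold higher [2.95, 3.32], whereas sox19a was 2.06-fold lower [1.996, 2.13]. Of 7 yolk syncytial layer genes 2 were higher, mxtx2 by 5.27-fold [4.01, 7.002]. Of 10 p53 response genes 2 were higher, casp8 by 3.24-fold [2.76, 3.81], and of 5 interferon genes only IRF7 was called, at 1.60 CPM against 0.472 CPM. Of 14 reference genes 3 were higher and 1 lower. The lower gene was b2m, which was 9.67-fold lower [7.13, 13.4]. The neuronal gene ELAVL3, the only measured gene of the list for tissues not formed at this stage, was at 3.08 CPM in MZdicer and 0.629 CPM in wild type.

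Among all genes, 2301 were at least 2-fold higher in MZdicer (MZdicer-high genes) and 819 lower (MZdicer-low genes), so 73.8% of the calls were higher. The highest named genes by the bound of the interval included the protease gene tmprss15 (624-fold, with 1 count in wild type [111, 24709]), LY75 (71.0-fold [58.0, 88.0]), NIBAN2 (ENSDARG00000008026, 76.3-fold [54.9, 109]), sh2d5 (54.5-fold [42.3, 71.3]) and BICC1 (68.0-fold [40.9, 122]). The lowest were ABLIM1, which had 0 counts in MZdicer and was at least 40.4-fold lower with MZdicer set to the floor of 3 counts (32.6-fold by the bound of the interval), olfcb1, which also had 0 counts and was at least 27.1-fold lower on the same floor (21.7-fold by the bound), dap1b (35.6-fold [20.3, 69.3]), ntd5 (26.0-fold [14.0, 54.6]) and FLNC (ENSDARG00000018820, 19.96-fold [11.99, 35.9]). LY75, NIBAN2, sh2d5 and BICC1 were at least 2-fold lower with the duplex than in MZdicer. tmprss15 was at 24.5 CPM in MZdicer, 20.01 CPM with the duplex, 29.2 CPM with the hairpin and 30.9 CPM with the 3xPS hairpin. It thus stayed far above its 0.0393 CPM in wild type after every injection, as did RAB14 and rtn3. For tmprss15, RAB14 and rtn3 too, a strain difference cannot be told apart from the loss of Dicer. With upper-quartile factors the median of all genes shifted by -0.19 on the log2 scale, and 1833 genes were higher and 1349 lower (57.6% higher). Longer genes had higher ratios across genes (Spearman correlation of gene length with the log2 ratio 0.189, genes not being independent replicates).

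The duplex comparison asks what mature miR-430 does to MZdicer embryos. No MZdicer library was injected with another RNA or a mock solution. An effect of injection itself therefore cannot be told apart from miR-430 in any comparison of an injected library with MZdicer. The miR-430 targets that were high in MZdicer were lower in the duplex library. ndr1 was 6.21-fold lower than in MZdicer [5.12, 7.57], CCNA1 5.19-fold lower [5.03, 5.36], lft2 4.93-fold lower [4.41, 5.51] and tdrd7a 2.41-fold lower [2.19, 2.64]. buc was 28.2-fold lower [23.9, 33.4], at 6.00 CPM against 7.36 CPM in wild type. MYF5 was 11.2-fold higher [4.205, 42.2] and mespaa 3.71-fold higher [2.74, 5.10]. Of 9 dorsal organizer genes OTX2 was higher (8.42-fold [4.58, 17.2]) and sebox lower (2.11-fold [1.94, 2.30]).

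All 6 literature targets had ratios below 1 in the duplex library against MZdicer, 4 of them called lower, with a median log2 ratio of -1.76 [-2.53, -0.04]. Of 28 maternal genes 6 were lower and 0 higher, including slbp2 (3.69-fold [2.71, 5.07]) and GDF9 (2.63-fold [2.15, 3.24]). Of 9 germ plasm genes 3 were lower, DAZL by 2.12-fold [1.81, 2.49]. Of 15 small RNA machinery genes 4 were lower and 0 higher, AGO1 by 6.25-fold [4.999, 7.88], CNOT7 by 3.12-fold [2.51, 3.89], ago3a by 2.998-fold [2.52, 3.58] and PAN2 by 2.58-fold [2.39, 2.79]. In the epiblast list nanog was 2.93-fold lower [2.82, 3.04] and sox19b 2.36-fold lower [2.24, 2.49]. Of 12 mesoderm and endoderm genes 3 were higher and 0 lower, including WNT8A (ENSDARG00000052910, 2.40-fold [2.07, 2.79]) and mespab (2.40-fold [1.92, 3.04]). Of 8 segmentation-stage markers 3 were higher and 0 lower, cdx4 by 2.35-fold [2.14, 2.57]. Of 10 p53 response genes 2 were lower, casp8 by 2.48-fold [2.14, 2.87] and cdkn1a by 2.23-fold [1.85, 2.69]. None of the 11 enveloping layer, 7 yolk syncytial layer, 5 BMP or 5 interferon genes was called. Of 14 reference genes 2 were lower, TBP by 3.65-fold [3.39, 3.93] and ubb by 2.09-fold [1.93, 2.26].

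In all, 212 genes were higher and 846 lower with the duplex. Other named genes with low values were BICC1 (56.5-fold [35.4, 95.9]), sh2d5 (24.8-fold [20.8, 29.7]), NIBAN2 (ENSDARG00000008026, 22.8-fold [18.9, 27.7]) and the RNA-binding protein gene LSM14B (19.8-fold [17.2, 22.8]). Those with high values included six4a (6.95-fold [4.49, 11.3]), SIX3 (ENSDARG00000054879, 8.33-fold [4.25, 18.6]), a forebrain regulator, and TBX3 (4.70-fold [3.25, 7.02]). RRM2 (ENSDARG00000078069), a ribonucleotide reductase gene that shares its symbol with another identifier, was at 149 CPM in wild type, 38.7 CPM in MZdicer, 0.316 CPM with the duplex, 10.02 CPM with the hairpin and 0.928 CPM with the 3xPS hairpin, so its values followed neither genotype nor injection alone. Of the 2301 MZdicer-high genes 2081 (90.4% [89.2, 91.6], Clopper-Pearson) were lower with the duplex than in MZdicer, with a median of -0.65 [-0.68, -0.61]. They stayed above wild type, with a median of 0.90 [0.87, 0.93] against 1.57 in MZdicer. Of the 819 MZdicer-low genes 85.2% were higher with the duplex, with a median of 0.45 [0.42, 0.50]. Both sets were chosen with the same MZdicer library. Libraries simulated with no injection effect against it, at assumed coefficients of variation between embryo pools of 0.1, 0.2 and 0.4, gave 56.9%, 59.98% and 65.8% lower for the MZdicer-high genes (medians -0.04, -0.10 and -0.30) and 63.9%, 69.0% and 73.3% higher for the MZdicer-low genes (medians 0.10, 0.21 and 0.47), so the MZdicer-low median did not exceed chance at 0.4, a setting that gave 1435 lower and 1466 higher calls for the duplex, more than the 846 and 212 observed.

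**Figure D1:**
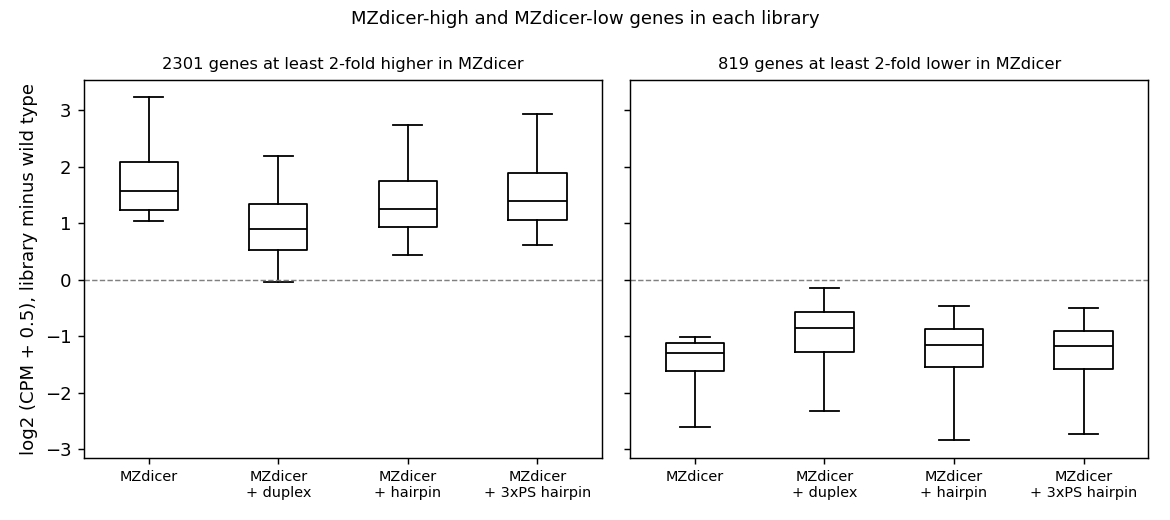
Box plots of the log2 difference from wild type (y axis, log2 of CPM plus 0.5) of the 2301 MZdicer-high genes and the 819 MZdicer-low genes in the MZdicer library and the 3 injected libraries; boxes span the quartiles with the median as a line, and whiskers the 5th to 95th percentile of genes. The medians of the MZdicer-high genes lie at 1.57 in MZdicer, 0.90 with the duplex, 1.25 with the hairpin and 1.40 with the 3xPS hairpin.

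The Ago2 hairpin comparison asks the same of a precursor that Ago2 cuts and that can then be trimmed. buc was 6.76-fold lower than in MZdicer [6.19, 7.39], sh2d5 21.8-fold lower [18.5, 25.9], BICC1 11.5-fold lower [9.16, 14.6] and the small RNA effector AGO1 3.58-fold lower [2.97, 4.31]. No literature target was called. lft2 was 1.96-fold lower [1.801, 2.13], tdrd7a 1.74-fold lower [1.60, 1.89], CCNA1 1.64-fold lower [1.60, 1.68] and ndr1 1.58-fold lower [1.396, 1.795], while lft1 and NANOS3 were 1.16-fold and 1.17-fold higher.

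Of 9 dorsal organizer genes 2 were higher with the hairpin, FOXA2 by 2.09-fold [1.83, 2.39] and OTX2 by 2.81-fold [1.45, 5.99], and GSC had a ratio of 1.94 [1.73, 2.17]. Of 12 mesoderm and endoderm genes only mespab was called, 2.16-fold higher [1.72, 2.74]; it and MYF5 (7.43-fold [2.73, 28.4]) were the called members of the 8 segmentation-stage markers. Of 28 maternal and 9 germ plasm genes only buc was called, and of 15 small RNA machinery genes only AGO1. No member of the Nodal, BMP, epiblast, enveloping layer, yolk syncytial layer, p53, interferon or reference lists was called. Across all genes 69 were higher and 280 lower, or 113 and 253 from the authors' RPKM values. Those were called without the counting interval and with a pseudocount of 0.1, which in CPM gave 131 higher genes. The named higher genes included gpbar1 (4.69-fold [2.73, 8.66]), bcam (3.84-fold [2.57, 5.94]) and TBR1 (2.98-fold [2.39, 3.75]). The named lower genes included AKR1B1 (ENSDARG00000045598, 13.5-fold [10.9, 16.9]), mtus1a (11.6-fold [9.72, 14.0]) and AMT (12.8-fold [9.28, 18.1]). Of the MZdicer-high genes 1881 (81.7% [80.1, 83.3]) were lower than in MZdicer, with a median of -0.30 [-0.32, -0.28], and 70.2% of the MZdicer-low genes were higher, with a median of 0.18 [0.14, 0.21]. Simulation with no injection effect at the same 3 coefficients of variation gave medians of -0.04, -0.10 and -0.30 for the MZdicer-high genes with 56.7%, 59.9% and 65.8% lower, and 64.0%, 69.5% and 73.4% of the MZdicer-low genes higher (medians 0.10, 0.21 and 0.48), so the MZdicer-low median did not exceed chance at 0.2 or 0.4, nor their share at 0.4, and the MZdicer-high median was level with chance at 0.4. The 0.2 setting gave 127 higher and 113 lower calls for the hairpin. Among 472 genes higher with the 3xPS hairpin than with the duplex, a set chosen without the MZdicer or hairpin library, the median of hairpin minus MZdicer was -0.55 [-0.59, -0.51].

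The 3xPS hairpin comparison asks the same of the hairpin that the submitters' labels call resistant to trimming; trimming itself was not measured in these libraries. lft2 was 2.21-fold lower than in MZdicer [2.03, 2.41] and was the only literature target called. ndr1 was 1.82-fold lower [1.59, 2.07], tdrd7a 1.41-fold lower [1.30, 1.53] and CCNA1 1.38-fold lower [1.35, 1.41]. buc was 6.27-fold lower [5.75, 6.83] and sh2d5 23.9-fold lower [20.1, 28.6]. The dorsal genes FOXA2 (2.19-fold [1.92, 2.51]) and frzb (2.06-fold [1.82, 2.34]) were higher.

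MYF5 was the only segmentation-stage marker called with the 3xPS hairpin, 4.83-fold higher [1.71, 18.8] than its 4 counts in MZdicer. No mesoderm, epiblast, enveloping layer, yolk syncytial layer, BMP, p53, interferon or small RNA machinery gene was called. AGO1 was 1.71-fold lower [1.47, 1.98]. b2m was 2.43-fold lower than in MZdicer [1.49, 4.002], the only called reference gene. Across all genes 64 were higher and 153 lower. Named higher genes included ONECUT2 (3.74-fold [2.63, 5.44]) and TBR1 (3.03-fold [2.43, 3.81]). Named lower genes included LSM1 (10.996-fold [8.07, 15.3]), AKR1B1 (ENSDARG00000045598, 9.23-fold [7.71, 11.1]) and SOD1 (6.65-fold [5.89, 7.53]). Of the MZdicer-high genes 1631 (70.9% [69.0, 72.7]) were lower than in MZdicer, with a median of -0.16 [-0.18, -0.15]; 68.0% of the MZdicer-low genes were higher, with a median of 0.17 [0.13, 0.20]. Simulation with no injection effect at the same 3 coefficients of variation gave 56.5%, 59.8% and 65.8% lower for the MZdicer-high genes (medians -0.04, -0.10 and -0.30) and 64.2%, 69.2% and 73.4% higher for the MZdicer-low genes (medians 0.10, 0.21 and 0.48), so the MZdicer-low values did not exceed chance at 0.2 or 0.4, nor the MZdicer-high median at 0.4. The 0.2 setting gave 125 higher and 111 lower calls for the 3xPS hairpin, of which the higher count is above the observed one. A coefficient of 0.166, set from the whole spread between the 3xPS and MZdicer libraries, gave 58.9% lower for the MZdicer-high genes (median -0.08). It was assumed equal for every gene, so values beyond it do not exclude chance. A set of 1198 genes higher with the duplex than in wild type was chosen without the MZdicer or 3xPS library. Of these, 994 were MZdicer-high, and the median of 3xPS hairpin minus MZdicer was 0.0150 [-0.00237, 0.0319]. With the duplex 11.5% of them were called lower than in MZdicer, against 32.6% of the MZdicer-high genes and 6.00% of all measured genes. Among 316 genes higher with the hairpin than with the duplex the median of 3xPS hairpin minus MZdicer was -0.28 [-0.32, -0.25].

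**Figure D2:**
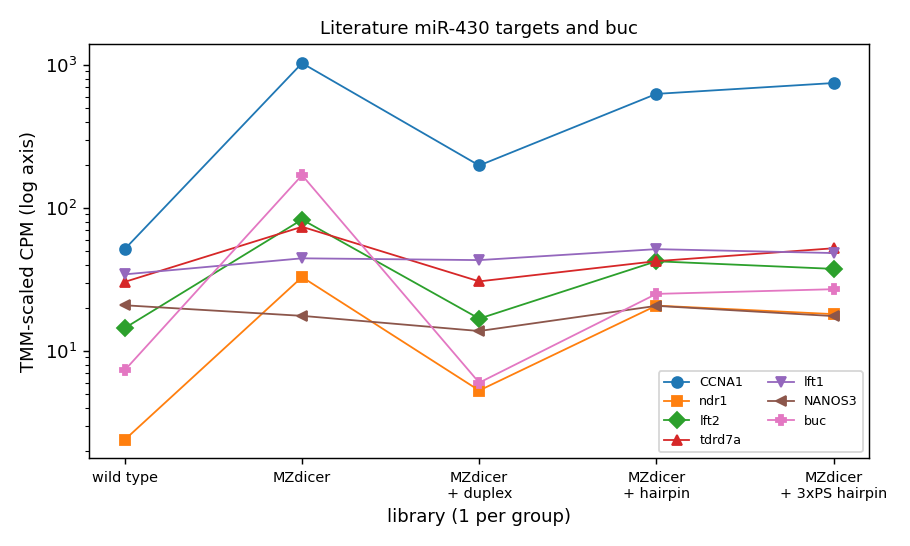
TMM-scaled CPM (log axis) of the 6 measured literature targets of miR-430 and of buc in each of the 5 libraries, 1 library per group; lines join the values of a gene. CCNA1 lies at 51.6 CPM in wild type, 1027 CPM in MZdicer, 198 CPM with the duplex, 626 CPM with the hairpin and 746 CPM with the 3xPS hairpin.

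The direct comparison of the 3xPS hairpin with the hairpin at the same stock concentration and volume asks whether the phosphorothioate bonds alter the response. AGO1 (ENSDARG00000092644) was 2.09-fold higher with the 3xPS hairpin [1.74, 2.53], ONECUT2 4.75-fold higher [3.46, 6.62], BICC1 3.67-fold higher [2.88, 4.71], ITGA10 3.54-fold higher [2.57, 4.95] and NIBAN2 (ENSDARG00000008026) 2.74-fold higher [2.48, 3.04]. For ITGA10 the hairpin library lay apart from MZdicer, at 2.03 CPM against 8.49 CPM in MZdicer and 7.19 CPM with the 3xPS hairpin. For ONECUT2 the 3xPS library did, at 9.24 CPM against 2.47 CPM in MZdicer and 1.95 CPM with the hairpin. None of the literature targets of miR-430 differed by 2-fold, and they went both ways. tdrd7a had a ratio of 1.23 [1.13, 1.34] and CCNA1 of 1.19 [1.17, 1.22], whereas ndr1 was 1.15-fold lower [1.01, 1.30] and lft2 1.13-fold lower [1.03, 1.24] with the 3xPS hairpin.

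The 6 targets had a median log2 difference of -0.13 [-0.23, 0.30] between the hairpins. In the small RNA machinery list AGO1 was called, DROSHA had a ratio of 1.46 [1.26, 1.70] and XRN1 of 1.30 [1.26, 1.35], with a list median of 0.21 [0.15, 0.38]. No member of any other list was called. The 14 reference genes had a median of -0.19 [-0.30, -0.06], 13 of them below 0, and all 5 BMP and ventral genes were below 0, with a median of -0.33. The ventral gene eve1 was 1.4985-fold lower [1.39, 1.61], the periderm keratin gene cyt1 1.35-fold lower [1.30, 1.41] and the reference gene RPLP0 1.23-fold lower [1.20, 1.27] with the 3xPS hairpin. Across all genes 70 were higher and 21 lower. The lower count was 37 after thinning and 40 from the authors' RPKM values, called without the counting interval and with a pseudocount of 0.1. Lower named genes were RRM2 (ENSDARG00000078069, 10.8-fold [7.03, 17.4]), NRAP (19.1-fold [6.21, 95.4], from 3 counts) and EGLN3 (2.69-fold [1.99, 3.67]). The MZdicer-high genes had a median difference of 0.13 [0.12, 0.14], and 69.5% of them were higher with the 3xPS hairpin; the MZdicer-low genes had a median of -0.04 [-0.08, -0.01]. Gene length moved with this difference, with a Spearman correlation of 0.299 across genes and medians of -0.10 in the shortest and 0.12 in the longest of 4 equal classes of genes. Against MZdicer the correlation was -0.211 for the hairpin and 0.0383 for the 3xPS hairpin. Against the duplex it was -0.0432 and 0.171, so the library that carries the trend cannot be told.

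The hairpins were also set against the duplex at the same dose. With the hairpin lft2, CCNA1 and ndr1 were called higher than with the duplex, and the 6 literature targets had a median of 0.94 [0.25, 1.88]. With the 3xPS hairpin the median was 0.95 [0.16, 1.91], with 3 targets called higher. BLTP2 was 5.95-fold higher with the hairpin [5.39, 6.59] and 9.29-fold higher with the 3xPS hairpin [8.43, 10.3], and zcchc2 was 7.08-fold [6.13, 8.21] and 9.20-fold higher [7.98, 10.6]. BICC1 was 18.0-fold higher with the 3xPS hairpin than with the duplex [11.2, 30.8].

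With the 3xPS hairpin smad9 was 4.69-fold lower than with the duplex [3.67, 6.06] and msx1b 3.22-fold lower [2.65, 3.95]. Of 9 dorsal organizer genes OTX2 was lower (4.15-fold [2.88, 6.11]) and sebox higher (2.27-fold [2.11, 2.46]), with a median of 0.18 [-0.01, 0.58], and of 8 segmentation-stage markers only cdx4 was called, 2.78-fold lower [2.57, 3.01]. The mRNA-binding protein gene igf2bp1 was 2.40-fold lower with the hairpin than with the duplex [2.28, 2.52]. Of the small RNA machinery genes 1 was higher with the hairpin than with the duplex, and 4 with the 3xPS hairpin. Against the duplex 316 genes were higher and 113 lower with the hairpin, and 472 higher and 82 lower with the 3xPS hairpin. The MZdicer-high genes had medians of 0.36 [0.34, 0.38] and 0.49 [0.46, 0.51], and the MZdicer-low genes of -0.27 [-0.31, -0.24] and -0.29 [-0.35, -0.26].

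The genes lowered by the 3 injections overlapped. Of the genes called lower than in MZdicer, 211 were shared by duplex and hairpin (16.8 for independent lists), 123 by duplex and 3xPS hairpin (9.18) and 118 by both hairpins (3.04); sh2d5, AKR1B1, mtus1a and buc were in all 3 lists, which shared 108 genes. Of the higher genes 36, 38 and 27 were shared (1.04, 0.962 and 0.313 for independent lists). The log2 ratios correlated across genes with r = 0.691 for duplex and hairpin, 0.659 for duplex and 3xPS hairpin and 0.687 for the hairpins, with covariances of 0.156, 0.129 and 0.0913. Libraries simulated without an injection effect against the same MZdicer library gave a correlation of 0.555, a covariance of 0.0354 and about 0.05 shared lower genes at an assumed coefficient of variation of 0.1. At 0.2 they gave 0.521, 0.0905 and 9.15 shared lower genes for duplex and hairpin, with 25.85, 25.85 and 25.45 shared higher genes for the 3 pairs and 125 to 127 higher calls per injected library. At 0.4 they gave 0.506, 0.323 and 396.5 shared lower genes for duplex and hairpin, but also 1435 to 1441 lower and 1462 to 1466 higher calls per injected library, against 846 and 212, 280 and 69, and 153 and 64 observed, so that setting gives more calls than these libraries show. Part of the sharing may come from the shared MZdicer library, which has no replicate to split.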

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

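The tests of the gene length trend, of the duplex library and both of the hairpin library against chance in the MZdicer library, of stage, of the MZdicer-low genes, and the test of the 3xPS library in 316 genes were chosen after the results were seen.

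fthl28 (ENSDARG00000076221), a ferritin heavy chain-like gene, had opposite calls with the duplex and the hairpin. Its log2 ratio to MZdicer was -1.14 with the duplex and 1.13 with the hairpin. It was at 25.0 CPM in wild type, 4.88 CPM in MZdicer, 1.93 CPM with the duplex, 11.3 CPM with the hairpin and 7.55 CPM with the 3xPS hairpin. The duplex and hairpin values rest on 49 and 278 counts in 1 library each, and the cause of their difference was not tested.

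In the fractional count column, which the comparisons above do not use, 115 genes had at least 50 counts in sum and 0 in the whole-number column of every library. Of these, si:ch211-139k8.4 (ENSDARG00000094081) was 22.5-fold higher in MZdicer than in wild type, at 31.5 CPM of that column in wild type, 709 CPM in MZdicer, 158 CPM with the duplex, 328 CPM with the hairpin and 603 CPM with the 3xPS hairpin. ENSDARG00000086858, which has no symbol, was 4.60-fold higher in MZdicer, at 22.0 CPM against 4.78 CPM.

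The 2301 MZdicer-high genes were higher with the 3xPS hairpin than with the hairpin. A gene length trend as the whole cause is argued against, since removing the median of each length decile left a median of 0.0950 [0.0829, 0.108] of 0.129. The composition of the set in expression and length does not account for it either, the median ranking at percentile 100 of 2000 random lists matched on both, whose central range was -0.00404 to 0.0224. Less miR-430 activity in the 3xPS library is consistent with the length-adjusted median being 0.0919 higher in the 750 genes lowered by the duplex than in the other 1551 (0.158 [0.138, 0.186] and 0.0658 [0.0471, 0.0806]). The amount of active RNA delivered and chance between single libraries stay open as untested. The 14 reference genes had a median of -0.191 [-0.303, -0.0632] between the same libraries. The 6 literature targets went both ways, with a median of -0.132 [-0.232, 0.296], and include lft1 and NANOS3, which were not called in MZdicer. Their interval holds both 0 and 0.129, so they do not decide. Reduced activity without trimming is a hypothesis.

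The MZdicer-high genes were lower in the injected libraries, although the same MZdicer library both chose and measured them. For the duplex, chance in that library as the whole cause is argued against by the hairpin lying 0.357 [0.336, 0.381] above the duplex, which does not use it. Chance there is also argued against for the genes lowest with the duplex, in sets chosen without the MZdicer library or the library tested: the median of hairpin minus MZdicer was -0.549 [-0.595, -0.514] in 472 genes higher with the 3xPS hairpin than with the duplex (429 of them MZdicer-high), and the median of 3xPS hairpin minus MZdicer was -0.284 [-0.321, -0.252] in 316 genes higher with the hairpin than with the duplex (269 of them MZdicer-high). For the other MZdicer-high genes chance stays open for both hairpins. Of 1198 genes higher with the duplex than in wild type, 994 were MZdicer-high. In the test chosen in advance, the 3xPS hairpin gave 0.0150 [-0.00237, 0.0319] there, with 47.5% of the genes lower than in MZdicer. That interval includes 0, the outcome written in advance for chance. The hairpin gave -0.0670 [-0.0999, -0.0448] after removing length decile medians (-0.111 [-0.130, -0.0799] before). These hairpin intervals lie below 0, unlike that of the 3xPS hairpin. The adjusted one did not clear the bound set for it after the results were seen, so the hairpin stays undecided. The 1198 genes had stayed high with the duplex. Of them 11.5% were called lower with the duplex, against 32.6% of the MZdicer-high genes and 6.00% of all measured genes. A median near 0 there, as for the 3xPS hairpin, cannot tell chance from a set short of genes that miR-430 lowers. Lowering by both hairpins may thus hold for genes that answer to the duplex. A later stage of the injected embryos cannot be told apart from the injection, the lowest median of the segmentation-stage markers over the 3 injected libraries being 0.202 above MZdicer. Without a library injected with another RNA, an effect common to any injection was not tested.

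Many MZdicer-low genes stayed low after injection, 268 of 819 being called lower than wild type in all 3 injected libraries; ABLIM1 was at 8.10 CPM in wild type and at 0.0812 CPM or less elsewhere. A chance low value in the MZdicer library is argued against by 53.6% of the MZdicer-low genes being called lower than wild type in both hairpin libraries. Over all MZdicer-low genes the medians of hairpin and 3xPS hairpin minus wild type were -1.15 and -1.17. The interval of the share [50.1, 57.1] was only just above the 50% set for it after the results were seen. It treats genes as independent and does not cover variation between libraries. A strain difference between the wild-type and MZdicer fish cannot be told apart from the genotype, because every MZdicer library shares both; the median of duplex minus wild type over the MZdicer-low genes was -0.854. Chance in the single wild-type library and a stage difference between MZdicer and wild type stay open and were not tested.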

How the results depend on the processing

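No paired analysis was possible because each group has 1 library. The planned miR-430 site and hexamer comparisons were not run. No called list median or value of the MZdicer gene sets changed direction; single named genes were not run under the alternatives. Of 168 alternative counts of genes 123 stayed within 1.5 times the main count, 24 were larger and 21 smaller. Of 192 alternative values of the MZdicer gene sets 137 stayed within their interval, and of 560 list medians 559. Lists of 5 genes have no median interval and were set against the range of their members. The list of 1 gene was set against its counting interval. Intervals of small lists are wide, so the list medians had little room to leave them. Counts follow the threshold, the filter and the pseudocount by construction; for the other shifts the cause was not tested. In each pair below the higher count comes first, in the order MZdicer against wild type, duplex, hairpin and 3xPS hairpin against MZdicer, 3xPS hairpin against hairpin, hairpin against duplex, and 3xPS hairpin against duplex. The 1.5-fold threshold gave 3806 and 2337, 871 and 1782, 421 and 985, 420 and 607, 541 and 193, 1089 and 674, and 1313 and 511 genes. A mean CPM of at least 5 gave 435 lower for MZdicer against wild type, 113 higher with the duplex, 27 and 173 with the hairpin, 19 and 95 with the 3xPS hairpin, 36 and 9 between the hairpins, and 49 and 36 lower for the hairpin and 3xPS hairpin against the duplex. A pseudocount of 2 CPM gave 496 lower for MZdicer, 99 higher with the duplex, 15 and 163, 11 and 96, 19 and 4, 196 and 35, and 32 lower for the 3xPS hairpin against the duplex. A pseudocount of 0.1 CPM gave 131 higher with the hairpin, 130 with the 3xPS hairpin, 138 and 37 between the hairpins, and 198 and 135 lower against the duplex. Upper-quartile factors gave 1349 lower in MZdicer, the authors' RPKM 113 higher with the hairpin and 40 lower between the hairpins, and thinning 37 lower between the hairpins. The share of MZdicer-high genes lower with the duplex was 88.2% with upper-quartile factors, 92.8% at a mean CPM of 5, 89.0% and 93.8% with pseudocounts of 0.1 and 2, and 87.7% when the MZdicer counts were split between selection and measurement. For the hairpin it was 79.3% by total counts, 85.2% with pseudocount 2, 78.2% from RPKM, 80.0% after length adjustment and 77.7% with the split; for the 3xPS hairpin it was 73.0% with pseudocount 2 and 68.2% with the split. The median of 3xPS hairpin minus hairpin in the MZdicer-high genes was 0.103 by total counts, 0.0980 from RPKM and 0.106 after length adjustment with the genes chosen anew; the small RNA machinery median between the hairpins was 0.147 after length adjustment. Depth limits low genes most in MZdicer, the smallest library.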

Other observations

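LSM1, a decay factor gene, was at 20.9 CPM in MZdicer, 1.11 CPM with the duplex, 2.64 CPM with the hairpin and 1.90 CPM with the 3xPS hairpin. LSM14B was at 172 CPM in MZdicer, 8.68 CPM with the duplex, 33.4 CPM with the hairpin and 32.5 CPM with the 3xPS hairpin. sh2d5 was alike in the 3 injected libraries, at 5.37 CPM with the duplex, 6.09 CPM with the hairpin and 5.57 CPM with the 3xPS hairpin against 133 CPM in MZdicer, whereas BICC1 was at 0.710, 3.49 and 12.8 CPM against 40.1 CPM. ONECUT2 was at 6.91 CPM with the duplex, 1.95 CPM with the hairpin and 9.24 CPM with the 3xPS hairpin against 2.47 CPM in MZdicer.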
